A study of Mus musculus with 4 samples.

How the data were processed

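The series holds 4 samples from mice with B16 melanoma: an RNA library and a receptor library of T cells from tumor, and an RNA library and a receptor library of T cells from lymph node. Each library stands alone in its group, so there were no replicates. Per the labels' protocols the cells were processed with 10x Genomics 5′ chemistry and 8100 cells entered library preparation. Per the submitters' processing notes, Cell Ranger 3.1.0 and the mouse build mm10 were used. The gene values are raw UMI counts per gene and cell, as the authors deposited them, with both libraries in a single table of 14721 genes and 10558 cells. Every value was checked to be a whole number at or above 0. The second deposited table is an annotation with other values (not counts) per cell: the library, the authors' cell label, a clonotype name and the CDR3 amino acid sequences. The rule behind the cell labels and the filters applied before deposition are not given in the sources used here. No cell in the table had fewer than 503 UMIs, more than 2997 genes or more than 5.00% mitochondrial counts.

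The final 1756 genes of the table held no UMI in any tumor cell. In all, 1768 genes were 0 throughout the tumor library and 841 throughout the lymph node library. Among 8653 genes with at least 100 lymph node UMIs, receptor segments aside, 46 were 0 throughout the tumor library. Whether a filter on rarely detected genes was applied to each library apart is not given in the sources used here, so no fold is given for genes with 0 UMIs in all tumor cells and they are described as listed at 0, although they took part in the ranking of ratios and in the counts.

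Counts were summed over the cells of each group and scaled to the total UMIs of the group, in the usual unit CPM. Groups were compared by the log2 ratio of CPM plus 1. Intervals of a ratio are exact conditional intervals for a pair of Poisson counts, without the added 1, at 95% confidence. Shares of cells carry exact Clopper-Pearson 95% intervals. With 1 RNA library per tissue no test between animals was possible, no p-values were computed, and all intervals cover counting error only. A gene was counted when it had 20 CPM or more in either group and called higher or lower at 2-fold. Receptor variable, diversity and joining segments were left out of the counts, and so were Cd4, Cd8a and Cd8b1 where they define the groups compared. A count of 0 was given a floor of 3 UMIs.

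Tumor Tdp-labelled cells were compared with tumor Cd4-labelled cells, both restricted to cells whose receptor carried a transgenic chain, and the tumor library with the lymph node library. These comparisons, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. Comparisons of tumor with lymph node Cd4-labelled cells and of lymph node Cd8- with Cd4-labelled cells were added after the data were seen, which makes 4 comparisons. A planned comparison of transgenic with endogenous tumor cells, and of endogenous tumor cells with lymph node cells, could not be made because no endogenous receptor was found among tumor cells. Cells were also classed by UMIs: double positive with at least 1 UMI of Cd4 and 1 of Cd8a or Cd8b1, CD4 single positive, CD8 single positive, or none of the 3 genes. These classes were called on all UMIs and on cells thinned to 2000 UMIs.

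Named genes were, per comparison, the 12 with the highest and the 12 with the lowest ratios among genes with 50 CPM or more in the higher group and 100 or more UMIs in all. Receptor segments, predicted, mitochondrial, ribosomal protein and Y-linked genes and Xist were left out of the naming. Members of the gene lists were named as examples of their list. There were 29 lists with 303 genes, of which 282 were in the table. They cover CD4 helper lineage, CD8 and cytotoxic lineage, lineage transcription factors, exhaustion, naive cells, stem-like progenitors, regulatory T cells, follicular, type 1, type 2 and type 17 helper cells, tissue residency and T cell receptor signalling. Others cover proliferation, type I interferon response, glycolysis, antigen presentation, apoptosis, dissociation stress, and markers of natural killer, gamma delta T, B, macrophage, neutrophil, dendritic, melanoma, fibroblast, endothelial and erythroid cells. For each list with 3 or more members at 20 CPM, the median log2 ratio was placed among 10000 random lists of equal size, drawn from 20 bins of mean expression. That percentile describes these libraries and is not a test.

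Alternatives were TMM scaling, a total without receptor, mitochondrial and ribosomal protein genes, the mean of each cell's CPM, and thinning to 2000 UMIs. The CPM minimum was dropped or set to 50, and the pseudocount was set to 10. Cells were left out by mitochondrial share (10%) or gene number (500), as called doublets, as cycling, or for B cell, myeloid or melanoma markers. Tumor classes were also drawn from UMIs in place of the labels. The scrublet doublet caller called 4 tumor cells (0.0718%) and 1 lymph node cell (0.0200%). Whether it missed doublets or few were left after the unknown filters before deposition cannot be told, so leaving these cells out tests little. The procedure was tested on simulated counts with known folds at the depth of these groups. In the comparison of tumor Cd4- with lymph node Cd4-labelled cells 49 of 50 genes lowered to 0.4 of their level were recovered. In every other setting of fold and comparison all 50 were, and 95.5% to 96.0% of the intervals held the true ratio. The counts were simulated as Poisson counts, which the intervals assume, so this coverage does not show whether the intervals hold under spread between cells. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.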

Results

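Gene expression and T cell receptors were measured in single T cells of mice carrying B16 melanoma, a transplantable mouse skin tumor. Per the labels' protocols, CD4 T cells with a transgenic receptor for TRP1, a melanocyte protein, were transferred after a single cyclophosphamide dose of 250 mg/kg, and tissue was taken on day 11 after transfer. The labels also give the treatment as untreated. The tumor RNA library held 5570 cells and 33147030 UMIs, with a median of 5862.5 UMIs and 1812 genes per cell. The lymph node RNA library held 4988 cells and 29067001 UMIs, with medians of 5596.5 UMIs and 1593.5 genes. Ribosomal protein genes took a median of 29.1% of a cell's counts in tumor and 43.7% in lymph node, and mitochondrial genes took 2.04% and 3.05%. Each tissue had 1 RNA library, so no value below has a replicate, and every interval covers counting error only.

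Cells with UMIs of both coreceptors made up a larger share of the tumor than of the lymph node library. All tumor cells with a receptor call carried a transgenic chain, whereas the lymph node samples' titles name endogenous cells. Tissue and cell origin therefore cannot be told apart in this contrast, which does not settle where CD4+CD8+ cells are found. The authors' labels called 2693 tumor cells Tdp (48.3%, exact Clopper-Pearson 95% interval 47.0% to 49.7%) and 2451 Cd4 (44.0%, 42.7% to 45.3%). A further 406 tumor cells were labelled Tcell, 19 Treg and 1 Cd8. The lymph node library held 2788 cells labelled Cd8 (55.9%, 54.5% to 57.3%), 1873 labelled Cd4 (37.6%, 36.2% to 38.9%), 321 labelled Treg and 6 labelled Tdp. What Tdp stands for is not given in the sources used here. Among tumor Tdp cells 78.5% had a Cd4 UMI, 90.9% a Cd8a UMI and 94.7% a Cd8b1 UMI, at a median of 6633 UMIs. Tumor Cd4 cells had Cd8a in 2.82% of cells (2.20% to 3.55%) at a median of 5533 UMIs, and lymph node Cd4 cells in 1.39% (0.909% to 2.03%) at a median of 4763 UMIs; at 2000 UMIs per cell these shares were 1.65% and 0.718%. Cd8b1 was seen in 9.83% and 9.77% of these cells. Free RNA was not estimated, so single UMIs are not proof of transcription. By UMIs alone, 41.9% of tumor cells (40.6% to 43.2%) and 3.81% of lymph node cells (3.30% to 4.38%) were double positive. At an equal depth of 2000 UMIs, which left out 257 tumor and 100 lymph node cells, the shares were 21.6% and 1.21%. By label, 75.3% of tumor Tdp, 9.06% of tumor Cd4, 5.07% of lymph node Cd4 and 2.04% of lymph node Cd8 cells were double positive. The labels describe all 4 samples as sorted CD4 and double positive cells, whereas 55.2% of lymph node cells had Cd8a or Cd8b1 UMIs and none of Cd4. The sort gates are not given in the sources used here, so shares of cells cannot be read as shares in the tissue.

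**Figure D1:**
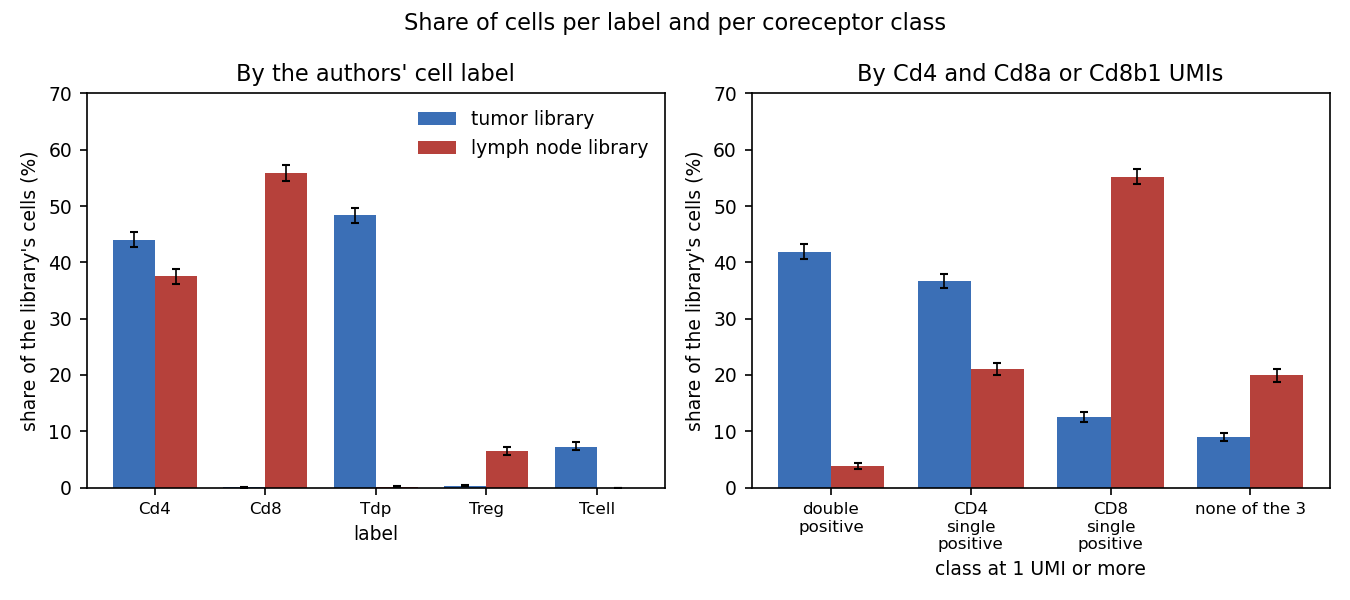
Bars give the share of each library's cells (percent) per authors' label and per class called at 1 UMI of Cd4 and of Cd8a or Cd8b1; error bars are exact 95% binomial intervals. Tdp-labelled cells were 48.3% of the tumor library and 0.120% of the lymph node library.

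Every tumor cell with a receptor call carried the same receptor, in Tdp- and Cd4-labelled cells alike, and no lymph node cell carried it. The receptor's alpha chain had the CDR3 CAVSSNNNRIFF and its beta chain the CDR3 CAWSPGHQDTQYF. All 5540 called tumor cells had it (100%, 99.9% to 100%), with both chains in 5184, the beta chain alone in 350 and the alpha chain alone in 6. They included 2682 Tdp, 2435 Cd4, 403 Tcell and all 19 Treg cells. In the lymph node library 0 of 4769 called cells had either chain, which allows a share of up to 0.0773% in this library. The lymph node samples' titles name endogenous cells only. This absence may therefore have been set by the design, and it does not show whether transgenic cells were present in lymph node. Its receptors were diverse, with 4746 distinct receptors in 4769 cells (99.5%, 99.3% to 99.7%) and at most 3 cells per receptor. Of the receptors seen in 2 or more lymph node cells, 12 were shared among Cd8 cells only, 3 among Cd4 cells only, 2 among Treg cells, 1 among Tdp cells, 1 between Cd4 and Cd8 cells and 1 between Cd4 and Tdp cells. Trbv31, the beta segment of the transgenic receptor, took 3.12% of all tumor UMIs. Although the tumor samples' titles name transgenic and endogenous cells, no tumor cell with UMIs of other Trbv segments alone was found, against 88.0% of lymph node cells. UMIs of both Trbv31 and another Trbv segment were found in 770 tumor cells.

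Tdp-labelled tumor cells had higher levels of cytotoxic genes and lower levels of helper genes than the Cd4-labelled cells that shared their receptor. This addresses how double positive cells differ from the CD4 cells they accompany only as far as the label stands for them. By UMIs, 75.3% of Tdp cells were double positive and 20.6% CD8 single positive. The granule protease gene Gzma stood at 107 CPM in Tdp and 4.10 CPM in Cd4 cells, 26.0-fold higher (log2 ratio of CPM 4.32 to 5.11). Of the 57 Gzma UMIs in Cd4 cells, 49 came from the 69 cells with a Cd8a UMI (86.2 CPM, seen in 8.70% of them), and the 2184 cells without a Cd8a or Cd8b1 UMI stood at 0.656 CPM. Ccl5, a chemokine that draws T cells, reached 19627 against 2056 CPM (9.55-fold), the pore-forming perforin gene Prf1 209 against 23.6 CPM (8.84-fold) and the granzyme gene Gzmb 3055 against 491 CPM (6.22-fold). On the other side, Tnfsf11, which encodes the cytokine RANKL, was 39.8-fold lower in Tdp cells, at 3.08 against 122 CPM (log2 ratio of CPM −5.73 to −4.93). Cd40lg, the CD40 ligand through which helper T cells activate B cells and dendritic cells, was 23.7-fold lower, at 6.87 against 163 CPM. In mm10 Gzma lies on chromosome 13 at 113093824 to 113100981, Ccl5 on chromosome 11 at 83525778 to 83530518, Tnfsf11 on chromosome 14 at 78277446 to 78308043 and Cd40lg on chromosome X at 57212143 to 57224042.

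Further genes with the highest ratios in Tdp cells were Gzmk, another granzyme (78.8 against 12.1 CPM), Cd160, a receptor of cytotoxic lymphocytes (94.9 against 11.7 CPM), and Ly6c2, a surface protein of memory CD8 T cells (2738 against 828 CPM). The kinase genes Lrrk1 (65.1 against 19.0 CPM) and Matk (91.5 against 31.2 CPM), the sialyltransferase gene St3gal6 (88.6 against 26.1 CPM), Wdr95 (104 against 24.9 CPM) and Armc7 (115 against 36.9 CPM) completed the set. Among the genes lowest in Tdp cells were Tnfrsf4, which encodes the costimulatory receptor OX40 (127 against 1054 CPM), the cytokine gene Tnfsf8 (4.18 against 53.5 CPM), and the chemokine receptor gene Ccr8 (4.78 against 89.2 CPM) with the gene of its ligand, Ccl1 (2.75 against 78.8 CPM). Izumo1r, the folate receptor 4 gene of regulatory and follicular T cells (11.4 against 74.2 CPM), Cd200, an inhibitory surface ligand (5.11 against 51.6 CPM), and the tetraspanin gene Cd9 (4.07 against 96.0 CPM) were lower as well. So were Ramp3 (4.51 against 58.0 CPM), Igfbp7 (6.10 against 63.7 CPM) and Nrgn (9.18 against 66.3 CPM).

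Of 19 measured members of the cytotoxic list, leaving out the coreceptor genes, 17 were above 0 and 7 were at least 2-fold higher in Tdp cells, with a median log2 ratio of 0.72, above all 10000 random lists. Examples beyond those named were the activating receptor gene Klrk1 (489 against 185 CPM), the T-box factor gene Eomes (42.4 against 9.50 CPM) and the granule gene Nkg7 (3585 against 2380 CPM). All 7 measured members of the helper list were below 0 and 4 were at least 2-fold lower in Tdp cells, with a median of −1.65, below all random lists. They included Zbtb7b, which encodes ThPOK, the transcription factor that directs CD4 lineage choice (9.35 against 31.5 CPM), Gata3 (34.9 against 53.6 CPM), and the costimulatory receptor genes Icos (212 against 366 CPM) and Cd28 (376 against 606 CPM). Runx3, which directs the CD8 lineage, was not higher in Tdp cells (81.4 against 107 CPM). In the list of lineage transcription factors 12 of 13 members were below 0, with a median of −0.54, and Tox stood at 29.1 against 76.8 CPM.

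The follicular helper list had a median of −2.60 over 5 members (−1.61 over 7 with members of 5 CPM), with the helper cytokine gene Il21 at 3.13 against 33.0 CPM. The regulatory T cell list had a median of −1.11 over 7 members (−1.83 over 10 with members of 5 CPM). Its Tnfrsf18, the gene of the costimulatory receptor GITR, stood at 198 against 430 CPM and its Il2ra at 83.0 against 84.7 CPM. Foxp3, the regulatory T cell factor gene, was below the CPM minimum, at 0.275 against 0.504 CPM. The lists overlap: the helper list shares Tnfrsf4 and Izumo1r with the regulatory list, and Icos and Izumo1r with the follicular helper list. In glycolysis 14 of 15 members were below 0 (median −0.49), among them Tpi1 (157 against 387 CPM) and Ldha (737 against 1081 CPM). The lists of early T cell receptor signalling (median −0.42, 8 of 11 members below 0) and dissociation stress (−0.37, 11 of 13 below 0) were lower too. Both hold immediate early genes and share Egr1, while Dusp1 (191 against 470 CPM) is a member of the stress list only. Type I interferon genes had a median of 0.41 with 9 of 12 members above 0, led by Ifit3 (34.1 against 6.34 CPM) and the antiviral gene Mx1 (33.3 against 12.5 CPM). With classes drawn from UMIs in place of labels that median was 0.015, inside the random range, and Ifit1 and Isg15 changed sign. Tissue residency genes had a median of 0.16, above the random range, including the integrin gene Itga1 (28.0 against 6.48 CPM), but 0.10 and inside that range at 2000 UMIs per cell. Of the 4 natural killer genes (median 2.10) 3 were at least 2-fold higher, Gzma, Eomes and the receptor gene Klre1 (45.9 against 9.50 CPM), and 1 lower, the signalling chain gene Fcer1g (10.6 against 37.5 CPM).

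Medians of the exhaustion (−0.07, 17 members), type 1 helper (−0.18, 11 members), naive (0.05, 5 members), stem-like (0.07, 4 members), proliferation (−0.13, 7 members), antigen presentation (−0.05, 8 members) and apoptosis (−0.05, 11 members) lists lay inside the middle 95% of random lists. With members of 5 CPM the naive median was −0.48 over 9 members and the stem-like median −0.88 over 8, both below that range. Tbx21, the master factor of type 1 helper cells, stood at 180 against 172 CPM, and the inhibitory receptor gene Lag3 at 742 against 705 CPM. Pdcd1, which encodes PD-1, stood at 280 against 197 CPM. Fewer than 3 members of the type 2, type 17, B cell, macrophage, gamma delta T, neutrophil, dendritic, melanoma, fibroblast, endothelial and erythroid lists reached 20 CPM, so no median was taken for these at that level, here or between the libraries.

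The contrast was also visible cell by cell. Gzmb was seen in 97.0% of Tdp and 47.3% of Cd4 tumor cells, at median depths of 6633 and 5533 UMIs, and in 0.160% of lymph node Cd4 cells at 4763 UMIs. Prf1 was seen in 61.1%, 9.14% and 5.82% of these cells, and Klrk1 in 89.5%, 40.1% and 0.107%. Cd40lg was seen in 48.6% of Cd4 and 2.82% of Tdp tumor cells, against 4.56% of lymph node Cd8 cells at a median of 6306 UMIs. Among Tdp cells it was seen in 26.6% of the 109 cells without a Cd8a or Cd8b1 UMI and in 1.83% of those with one. Tnfrsf4 was seen in 91.8% of Cd4 and 31.3% of Tdp tumor cells, against 4.73% of lymph node Cd8 cells. Gzma was seen in 10.5% of Tdp cells, 0.449% of tumor Cd4 cells (0.224% to 0.802%) and 0.801% of lymph node Cd4 cells (0.449% to 1.32%). At 2000 UMIs per cell the shares in Tdp and Cd4 tumor cells were 92.4% and 34.9% for Gzmb, 29.3% and 3.47% for Prf1, 57.8% and 23.1% for Klrk1, 1.01% and 23.8% for Cd40lg, 15.02% and 75.6% for Tnfrsf4 and 7.13% and 0.290% for Gzma. The lymph node Cd4 shares at that depth were 0.0552% for Gzmb, 2.98% for Prf1, 0.0552% for Klrk1 and 0.552% for Gzma, and the lymph node Cd8 shares 2.35% for Cd40lg and 2.21% for Tnfrsf4.

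Counted over 4817 genes, 57 were at least 2-fold higher and 112 at least 2-fold lower in Tdp cells, and the median log2 ratio of all genes was −0.11. TMM scaling moved ratios by 0.12 and gave 75 and 90 genes, so that 45.5% of calls were higher in place of 33.7%. Both sides come from 1 library of an unknown number of animals, so animal-to-animal variation is unknown.

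**Figure D2:**
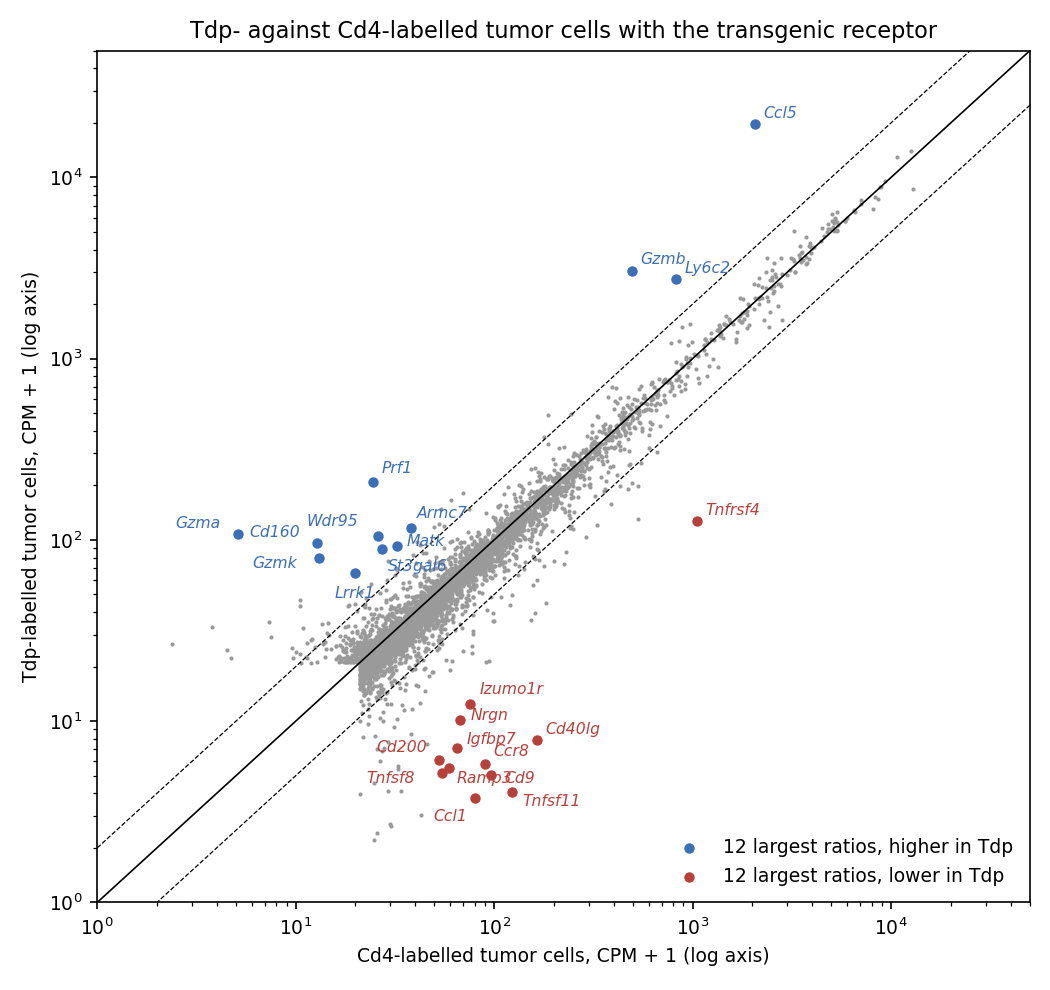
Each point is a gene with 20 CPM or more, at CPM plus 1 in Cd4-labelled (x) and Tdp-labelled (y) tumor cells, both on log axes; the solid line marks equality, dashed lines 2-fold, and the 12 highest and 12 lowest ratios are named. Ccl5 at 19627 against 2056 CPM and Tnfrsf4 at 127 against 1054 CPM lie far from the line on either side.

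Between the libraries of tumor and lymph node cells, Gzmb was 114-fold higher in tumor (1920 against 16.8 CPM) and Mt1, a metal-binding protein gene, stood at 1316 against 6.23 CPM. Lag3 and Havcr2, inhibitory receptor genes, stood at 715 against 12.5 CPM and at 130 against 0.998 CPM. Ccr7, the receptor gene that guides T cells into lymph nodes, was 67.3-fold lower in tumor (7.03 against 473 CPM). The tumor library held transgenic cells and the lymph node library endogenous cells, more than 50% of them labelled Cd8, so tissue, receptor, activation and cell type cannot be told apart in these ratios.

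Other genes with the highest tumor ratios were Mt2 (151 against 0.241 CPM), the secreted protein gene Spp1, osteopontin (228 against 1.17 CPM), the galectin gene Lgals3 (1073 against 10.2 CPM), the interferon-induced gene Ifitm1 (116 against 0.344 CPM), and AA467197 (128 against 0.378 CPM). Lilr4b (155 against 1.20 CPM) and Klrc1 (500 against 6.85 CPM), receptors that dampen lymphocyte or myeloid activation, the macrophage growth factor gene Csf1 (183 against 1.93 CPM) and the G protein regulator gene Rgs16 (910 against 14.0 CPM) followed. Of the genes ranked lowest, some are listed at 0 in all tumor cells, which is not read as low expression: Igfbp4 was listed at 0 in tumor against 745 CPM in lymph node, Tmem108 at 0 against 74.8 CPM and Ifngr2, a chain of the interferon gamma receptor, at 0 against 50.7 CPM. Dapl1 (1.60 against 336 CPM), Nsg2 (1.39 against 181 CPM), the transcription factor gene Klf3 (1.93 against 151 CPM), the Notch pathway gene Dtx1 (0.573 against 73.1 CPM) and the interleukin 6 receptor gene Il6ra (0.965 against 84.7 CPM) were low in tumor. Tdrp (0.815 against 75.2 CPM) and Rflnb (2.60 against 139 CPM) closed the set.

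By list, 15 of 16 exhaustion genes were at least 2-fold higher in tumor (median 3.17), among them Pdcd1 (241 against 14.3 CPM) and Tigit (420 against 32.1 CPM), while Tox, a factor of exhausted cells, stood at 49.7 against 49.2 CPM. In the cytotoxic list 16 of 22 members were 2-fold higher and 1 lower (median 2.54), with Ccl5 at 12135 against 602 CPM and Prf1 at 127 against 19.3 CPM. The integrin gene Itgae was the member that was lower (1.27 against 40.0 CPM). In the type 1 helper list 10 of 11 members were 2-fold higher (median 2.44), including Ifng (311 against 10.8 CPM), Tbx21 (175 against 11.7 CPM) and Bhlhe40, a factor needed for interferon gamma production (1080 against 27.6 CPM). Glycolysis genes had a median of 1.27 with 9 of 14 at least 2-fold higher, such as Tpi1 (254 against 39.5 CPM) and Gapdh (1032 against 341 CPM). All 14 naive genes were below 0 and 13 at least 2-fold lower (median −4.53). They included S1pr1, the receptor that lets T cells leave lymph nodes (9.84 against 163 CPM), and the transcription factor gene Lef1 (47.3 against 301 CPM). Igfbp4, listed at 0 in tumor, is counted among them. Stem-like genes had a median of −2.57 with 7 of 9 at least 2-fold lower, such as Tcf7 (8.09 against 318 CPM) and Id3 (2.38 against 102 CPM). Interferon genes had a median of −0.58 with 11 of 13 below 0, led by Ifit3 (21.7 against 69.5 CPM) and Oasl2 (3.56 against 41.9 CPM).

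Medians above the random range were also found for the regulatory T cell (1.20, 6 of 10 members at least 2-fold higher and 4 lower), helper (0.75, 8 members, Cd4 among them) and natural killer lists (2.24, 4 members); the helper median was 0.44 and inside that range at 2000 UMIs per cell. Foxp3, the regulatory T cell factor gene, was lower in tumor (2.14 against 28.5 CPM). The lineage factor list lay below the random range (−0.22, 15 members). Follicular helper (0.35, 5 members), residency (0.53, 7 members, but 1.01 and above the range at 2000 UMIs), receptor signalling (0.34, 11 members), proliferation (0.06, 8 members), antigen presentation (0.40, 8 members), apoptosis (0.40, 11 members) and dissociation stress (−0.00060, 13 members) medians lay inside the random range. Within the stress list Fos was lower in tumor (102 against 545 CPM). Counted over 4978 genes, 571 were at least 2-fold higher and 258 at least 2-fold lower in tumor, 4 of the latter listed at 0 there (68.9% of calls higher), with a median over all genes of 0.16. Scaling to a total without receptor, mitochondrial and ribosomal protein genes moved that median to −0.18 and gave 475 higher and 639 lower genes (42.6% higher).

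**Figure D3:**
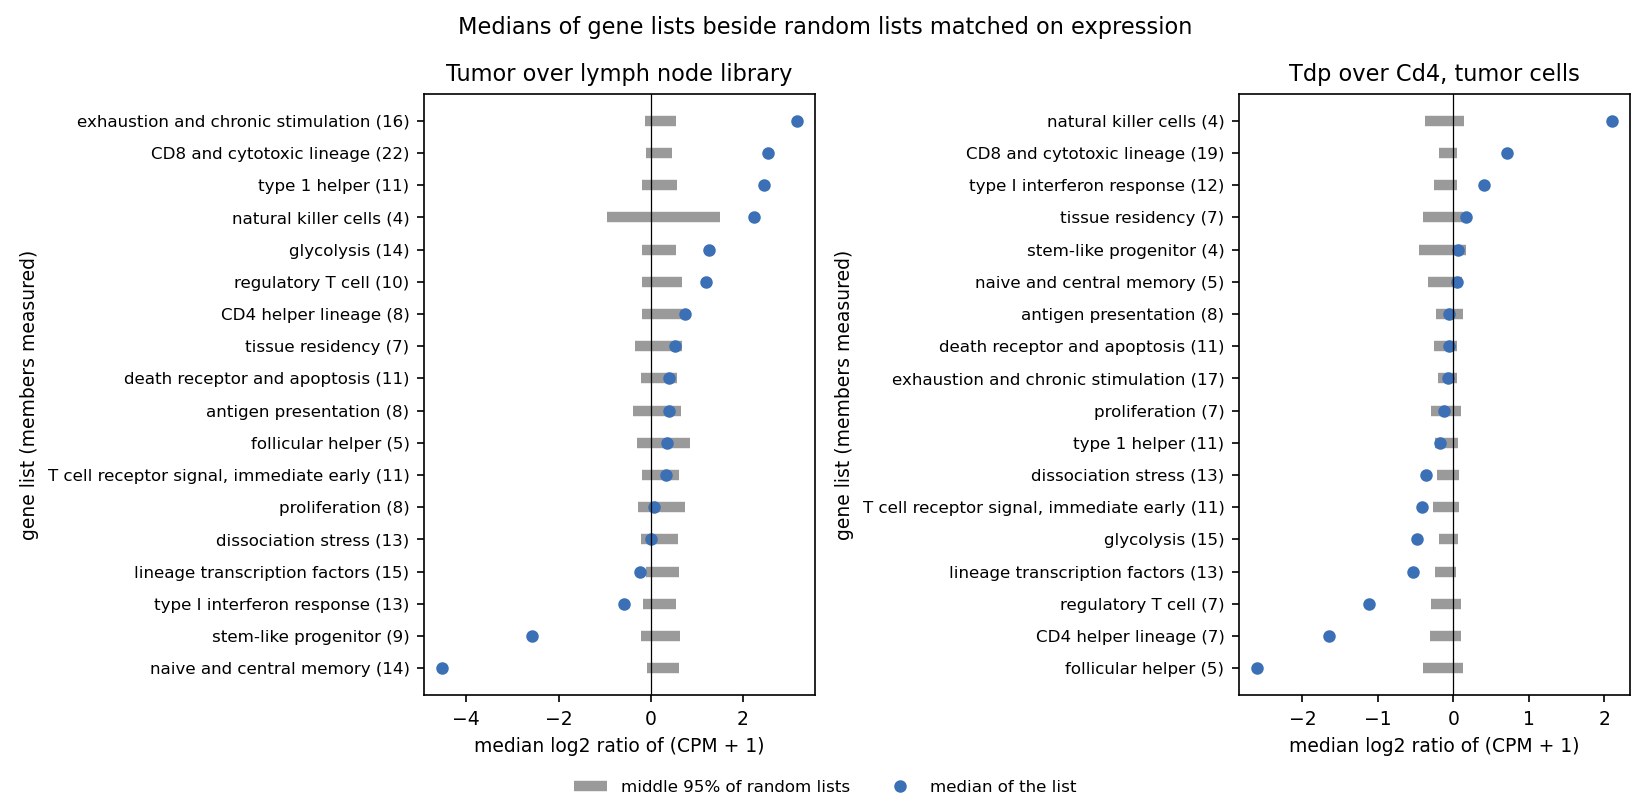
Points give the median log2 ratio of CPM plus 1 over each list's measured members, for the tumor over the lymph node library and for Tdp- over Cd4-labelled tumor cells; grey bars span the middle 95% of 10000 random lists matched on expression. The helper median lies at 0.75 in the first and −1.65 in the second, and the naive median at −4.53 and 0.05.

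Between Cd4-labelled cells of tumor and lymph node, a comparison added after the data were seen, cytotoxic and type 1 helper genes were far higher in tumor. Gzmb stood at 491 CPM in tumor and 1.22 CPM in lymph node Cd4 cells, Ifng at 348 against 1.22 CPM, Mt1 at 968 against 0.778 CPM, Lgals3 at 851 against 3.002 CPM and Rgs16 at 945 against 4.45 CPM. Plac8 (776 against 2.67 CPM), Csf1 (290 against 0.778 CPM), Klrc1 (405 against 1.78 CPM) and the calcium-binding protein gene S100a6 (3244 against 21.3 CPM) followed. Ifitm1 (177 CPM), Ifitm2 (160.1 CPM) and Serpinb1a, a granule protease inhibitor gene (152 CPM), had no UMI in lymph node Cd4 cells and were at least 530-fold, 480-fold and 454-fold higher against a floor of 3 UMIs over that group. The inhibitory receptor gene Lag3 stood at 705 against 10.6 CPM, Tbx21 at 172 against 1.22 CPM, and Tnfrsf4 at 1054 against 27.4 CPM. Cd40lg, high in both, stood at 163 against 121 CPM.

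Lower in tumor Cd4 cells were Dapl1 (2.52 against 289.7 CPM), Nsg2 (2.88 against 203 CPM), Ly6c1 (6.19 against 343 CPM), Il6ra (1.73 against 119 CPM) and Tcf7 (16.1 against 368 CPM). So were Trat1, a receptor-associated adaptor gene (0.576 against 81.9 CPM), Treml2 (0.216 against 57.6 CPM, from 3 tumor UMIs, log2 ratio of CPM −10.34 to −6.50), Rflnb (3.46 against 210 CPM) and the sodium pump gene Atp1b1 (1.01 against 92.5 CPM). Igfbp4 (1757 CPM in lymph node), Pdlim4 (130 CPM) and Ifngr2 (102 CPM) were listed at 0 in tumor. Of 7 measured members of the regulatory T cell list 6 were at least 2-fold higher in tumor Cd4 cells. The regulatory factor gene Foxp3, below the CPM minimum, was lower there, at 0.504 against 3.56 CPM. The cytotoxic (median 4.12), exhaustion (4.57), type 1 helper (5.24), regulatory T cell (3.17), residency (2.53) and glycolysis (1.80) lists lay above the random range. Naive (−4.45), stem-like (−2.74) and interferon (−0.82) lists lay below it. So did narrowly the lineage factor list (−0.11, percentile 2.36, and 2.82 with TMM scaling), and the other 7 with a median lay inside. The naive list includes Igfbp4, listed at 0 in tumor. Of 5139 genes 761 were at least 2-fold higher and 322 at least 2-fold lower, 6 of them listed at 0 in all tumor cells (70.3% higher, median of all genes 0.21). With the total that leaves out receptor, mitochondrial and ribosomal protein genes the counts were 640 and 794 (44.6% higher, median −0.16), and TMM scaling moved ratios by −0.12. Origin and tissue remain confounded, since these tumor cells are transgenic and these lymph node cells are not.

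Within the lymph node library, Cd8-labelled cells differed from Cd4-labelled cells in genes that partly matched those that set Tdp cells apart in tumor, a comparison also added after the data were seen. Nkg7 stood at 858 CPM in Cd8 and 31.1 CPM in Cd4 cells, Ly6c2 at 1118 against 14.2 CPM, Eomes at 51.8 against 1.78 CPM and Plac8 at 362 against 2.67 CPM. The cytokine receptor gene Il2rb (185 against 20.2 CPM), the lectin receptor gene Klrd1 (163 against 19.7 CPM), the cystatin gene Cst7 (189 against 27.7 CPM), Ctla2a (55.9 against 2.78 CPM), Lcn4 (67.0 against 3.78 CPM), Ahnak (102 against 8.12 CPM), S100a6 (232 against 21.3 CPM) and Hopx (65.1 against 7.78 CPM) were higher as well. Lower were Cd40lg (15.01 against 121 CPM), Igfbp4 (291 against 1757 CPM), Pdlim4 (3.20 against 130 CPM), Ly6c1 (10.2 against 343 CPM), Tmem64 (10.8 against 99.7 CPM), Dusp10 (51.6 against 270.3 CPM), Trat1 (19.0 against 81.9 CPM) and Trib2 (11.4 against 50.3 CPM). Ifngr2 (25.7 against 102 CPM), Tspan32 (37.5 against 134 CPM), Tgfbr3 (17.2 against 55.8 CPM) and Nxpe3 (18.7 against 59.5 CPM) were lower too.

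Of 4050 genes measured in both contrasts, 72 were at least 2-fold higher in lymph node Cd8 cells. In tumor these had a median Tdp over Cd4 log2 ratio of 0.46, above all random lists, and 54 were above 0. The 28 genes at least 2-fold lower in lymph node Cd8 cells had a median of −0.91 in tumor, below all random lists, and 25 were below 0. Predicted and ribosomal protein genes aside, 25 genes were at least 2-fold apart the same way in both tissues, among them Cd160, Eomes, Ccl5 and Ly6c2 on the higher and Zbtb7b, Cd40lg and Ramp3 on the lower side, and 2 went opposite ways. Zbtb7b stood at 2.32 against 31.0 CPM in lymph node. Over 4530 genes 96 were at least 2-fold higher and 65 lower in lymph node Cd8 cells. Leaving out cells with 2 or more B cell, myeloid or melanoma markers removed 222 Cd8 and 5 Cd4 cells and gave 95 genes higher and 63 lower. Of the 222 cells, 214 had Cd79b and Ighm. Cd79b was seen in 11.3% of all Cd8 and 0.214% of all Cd4 cells. Ighm was seen in 64.4% and 60.2% of them and Cd79a, another B cell receptor component, in 0.359% and 0.320%. Cytotoxic (median 2.51), type 1 helper (2.05), residency (1.46), exhaustion (1.34) and stem-like (0.75) lists lay above the random range, helper (−0.52), naive (−0.40) and lineage factor (−0.27) lists below it, and the other 9 inside.

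**Figure D4:**
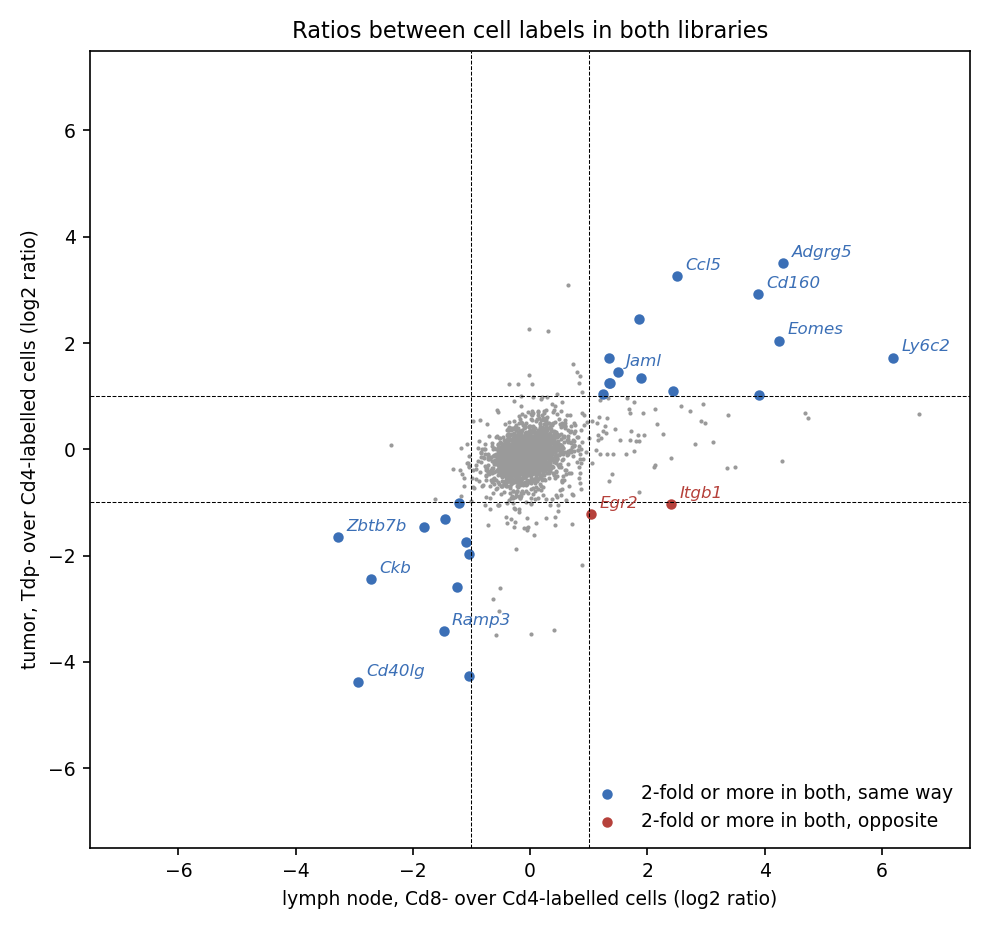
Each point is a gene measured in both contrasts, at its log2 ratio of Cd8- over Cd4-labelled lymph node cells (x) and of Tdp- over Cd4-labelled tumor cells (y); dashed lines mark 2-fold. Coloured points are the 25 genes at least 2-fold apart the same way in both and the 2 that went opposite ways, Egr2 and Itgb1.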

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

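Of the tests in this part, only that of Cd4 capture was chosen before its result was seen. The lymph node contrast used for the first genes below was added after the data were seen as well.

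A pair of genes went opposite ways in the tissues. Egr2, an early response factor gene, had a log2 ratio of −1.21 for Tdp over Cd4 cells in tumor (11.4 against 27.9 CPM) and 1.04 for Cd8 over Cd4 cells in lymph node (32.5 against 15.3 CPM). Itgb1, the integrin beta 1 gene, had −1.03 in tumor (68.5 against 141 CPM) and 2.41 in lymph node (95.9 against 17.2 CPM). Neither difference between tissues was tested, since each rests on 1 library. In cells outside the comparisons of labels, AY036118 reached 3805 CPM in tumor Tcell-labelled cells, against 502 CPM in Tdp and 532 CPM in Cd4 cells. The Tcell cells also had a median of 2040 UMIs, 816.5 genes and 3.1001% mitochondrial counts, against 6633 UMIs and 1.95% in Tdp and 5533 UMIs and 2.03% in Cd4 cells. Gzmb reached 169 CPM in lymph node Treg-labelled cells, against 1.22 CPM in Cd4 and 5.79 CPM in Cd8 cells.

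Cytotoxic genes were higher and helper genes lower in Tdp- than in Cd4-labelled tumor cells. In cells of 4000 to 8000 UMIs on both sides the cytotoxic median was 0.77, above all random lists. The ratios were already scaled to total UMIs, so this window adds little on the greater depth of Tdp cells as a cause. Doublets of a Cd4-labelled cell with another of about equal UMI content would leave helper genes no more than 2-fold lower, whereas the helper median was −1.65, and −1.22 or lower with any 1 member left out; partners richer in RNA were not tested. Labels drawn from the very genes that then differ are argued against by classes called from Cd4, Cd8a and Cd8b1 UMIs alone, in which the cytotoxic median was 0.64, again above all random lists. A difference in state between cells that do and do not transcribe Cd8 may therefore underlie the pattern, as a hypothesis found and tested in the same library.

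Type I interferon genes were higher in Tdp- than in Cd4-labelled cells. A Tdp label given to interferon-rich cells whatever their Cd8a and Cd8b1 UMIs could produce this: with classes from UMIs alone the list's median was 0.015, inside the random range, and among the 109 Tdp-labelled cells without a Cd8 UMI Ifit1 stood at 280.2 CPM, against 34.3 CPM in Tdp cells with one and 18.7 CPM in Cd4 cells without. The share of cells above the interferon level that 5% of Cd4-labelled cells exceed was 29.4% in those 109 cells (21.0% to 38.8%) and 3.93% in Tdp cells with a Cd8 UMI (3.21% to 4.75%). A stronger interferon response in cells that transcribe Cd8 cannot be told apart from this, because Tdp cells with a Cd8 UMI still had a median of 0.34 over Cd4-labelled cells, a group from which the labels may have drawn interferon-rich cells. The median cell went the other way, with 21.4 interferon UMIs per 10000 in Tdp cells with a Cd8 UMI and 25.8 in Cd4 cells without one.

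Of Tdp-labelled cells, 20.6% had Cd8a or Cd8b1 UMIs and no Cd4 UMI. Sparse capture of Cd4 is a candidate explanation, since 21.5% of Tdp cells lacked a Cd4 UMI (19.9% to 23.1%) where Poisson capture at their depths gives 17.2%, a ratio of 1.25. A separate CD8 single positive population among Tdp-labelled cells cannot be told apart from unequal Cd4 levels as a source of the excess. Between the 576 cells without and the 2106 with a Cd4 UMI 0 of 4558 genes were 2-fold apart. The median depths were 5788.5 and 6837 UMIs. By this estimate the excess makes up only 20.05% of the former, so a gene would have to be 5.99-fold higher in it to show. The estimate rests on the mean Cd4 level of all Tdp cells, which includes any cells that lack Cd4. The excess may therefore be larger and the fold needed smaller.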

How the results depend on the processing

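No paired analysis was possible because each tissue gave 1 RNA library and replicate numbers were assigned in accession order. Alternatives chosen after the data were seen are classes called on 1 UMI without labels, the window of 4000 to 8000 UMIs, leaving out Tcell cells, keeping cells without a receptor call, list members of 5 CPM, shares at 2000 UMIs, and all settings of the last 2 comparisons. Of 102 counts of genes under another setting, 80 stayed within 1.5 times the reported count. Without a CPM minimum more genes were counted: 1065 higher and 824 lower in tumor against lymph node, 199 and 334 in Tdp against Cd4, 1482 and 929 in tumor against lymph node Cd4, and 372 and 184 in lymph node Cd8 against Cd4. At 50 CPM fewer were: 353 and 126, 31 and 61, 453 and 171, and 42 and 29, in the same order. The total without receptor, mitochondrial and ribosomal protein genes gave 639 genes lower in tumor, 90 higher in Tdp, 794 lower in tumor Cd4 and 162 higher in lymph node Cd8 cells. Removing those genes raises CPM most where ribosomal protein genes take more, as in lymph node. A pseudocount of 10, which shrinks ratios of low genes, gave 31 genes higher in Tdp and 39 lower in lymph node Cd8 cells.

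Double positive shares fell with depth by construction: 21.6% of tumor and 1.21% of lymph node cells at 2000 UMIs, 10.9% and 0.342% at 1000, and 38.6% and 1.98% with at least 2 Cd8 UMIs. Distinct receptors were 97.4% of lymph node cells by beta chain alone. Of 2354 values of named genes 1702 were classed as the same, 645 moved but kept their direction and 7 reversed. The 7 reversals were all in interferon genes under classes from UMIs. Ifit1 went to −0.24 (at least 2 Cd8 UMIs), −0.23 (both Cd8 genes) and −0.064 (1 UMI). Isg15 went to −0.31, −0.32 and −0.27 in these settings, and to −0.27 with classes on thinned counts. The interferon median was 0.0075 with 2 Cd8 UMIs. No list outside the random range changed sign in 404 list values, but some of these values are percentiles, which cannot change sign. In Tdp against Cd4 cells the naive and stem-like medians, inside that range, went to −0.48 and −0.88 and below it with members of 5 CPM; the follicular helper median went to −1.61, above the regulatory T cell median of −1.83. That setting adds members with few UMIs. Residency, above the range, was inside it at 2000 UMIs (0.10), in cells of 4000 to 8000 UMIs (0.089) and with classes on 1 UMI (0.14). Between the libraries the helper median went inside the range with the mean of each cell's CPM (0.52), at 2000 UMIs (0.44) and with members of 5 CPM (0.58), while residency went above it (1.02, 1.01 and 1.07). In the Cd4 comparison of tissues lineage factors went inside with members of 5 CPM (−0.016, percentile 9.23), TMM (2.82) and the mean of each cell's CPM (3.44), and follicular helper above it with these (99.31, 97.52, 98.99) and at 2000 UMIs (97.90). Other marker lists had a median only with members of 5 CPM: B cells −2.42 between the libraries and 0.72 in lymph node, macrophages 0.59, 1.72 in Tdp against Cd4 (3 members, with Ly6c2 in the middle) and 0.45 in lymph node, and natural killer cells 2.76 between tissues in Cd4 cells and 2.42 in lymph node. In the Cd4 comparison receptor signalling went above with members of 5 CPM (0.73). In lymph node at 2000 UMIs receptor signalling went above (0.16) and apoptosis below (−0.31). The causes were not tested. Random lists not matched on expression placed 2 lists differently, both in the Cd4 comparison of tissues: lineage factors at percentile 4.12 and follicular helper at 98.89. Called doublets were too few to test that filter, and the mitochondrial limit removed no cell. Not run were the alternatives for comparisons with endogenous tumor cells, of which none were found, and Leiden clustering, since the authors' labels were used. The Trbv31 rule in place of the annotation found no endogenous tumor cell either. It leaves out cells with UMIs of both Trbv31 and another Trbv segment, which were 770 of 5570 tumor cells. Free RNA was not estimated, so the rule cannot exclude endogenous cells among these. Depth set the log2 half-widths of named genes with UMIs on both sides. They were at most 0.42 in Tdp against Cd4 (24 of 24 genes) and 1.18 between the libraries (21 of 24). They were at most 1.92 between tissues in Cd4 cells (18 of 24) and 0.76 in lymph node (24 of 24). Named genes with 0 UMIs on 1 side have no bounded half-width.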

Other observations

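Cells labelled Treg were few in tumor and more numerous in lymph node. The 19 tumor Treg cells, all with the transgenic receptor, had the regulatory factor gene Foxp3 at 664 CPM (84.2% of cells) and Ikzf2 at 574 CPM, with the inhibitory receptor gene Ctla4 at 1689 CPM and Tnfrsf4 at 3086 CPM. The 321 lymph node Treg cells had Foxp3 at 394 CPM (73.8% of cells), Ikzf2 at 683 CPM, Ctla4 at 845 CPM, Tnfrsf4 at 1236 CPM and Ccr8 at 198 CPM. Foxp3 stood at 0.275 CPM in tumor Tdp cells and 3.56 CPM in lymph node Cd4 cells. Gzmb stood at 1081 CPM in tumor Treg cells. It was seen in 13.7% of lymph node Treg cells. The 406 tumor Tcell cells, with a median of 2040 UMIs, had Gzmb at 1083 CPM, Ccl5 at 17381 CPM and Cd40lg at 49.8 CPM. The 6 lymph node Tdp cells had Cd8a and Cd8b1 UMIs and none of Cd4, with Ccl5 at 12944 CPM.

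In the 69 tumor Cd4-labelled cells that had a Cd8a UMI, with a median of 8120 UMIs, Gzmb stood at 1562 CPM, Ccl5 at 11027 CPM, Cd40lg at 66.9 CPM and Tnfrsf4 at 574 CPM. The 2184 Cd4-labelled cells without any Cd8a or Cd8b1 UMI, with a median of 5449.5 UMIs, had 441, 1648, 168 and 1079.9 CPM of these genes in that order. Tdp-labelled cells with such a UMI had Gzmb at 3101 CPM, Ccl5 at 19971 CPM, Cd40lg at 4.37 CPM and Tnfrsf4 at 114 CPM. Isg15 stood at 158 CPM in the 69 cells, 203 CPM in the 2184 and 217 CPM in the Tdp cells.

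Trdc, the constant gene of the delta receptor chain, had a UMI in 45.5% of the 5540 tumor cells with the transgenic receptor, in 55.6% of Tdp and 38.2% of Cd4 cells among them, and in 0.541% of lymph node cells; at 2000 UMIs per cell it was seen in 23.1% of Tdp, 19.5% of Cd4 and 0.327% of lymph node cells. Trdv4 was seen in 5.14% of these tumor cells. The gamma chain gene Tcrg-C1 stood at 0.091 CPM in them and 1.20 CPM in lymph node, and Tcrg-C4 at 9.13 CPM in Tdp and 0.648 CPM in Cd4 cells. Adgrg5, chosen after the values were seen, stood at 25.8 CPM in Tdp and 1.37 CPM in Cd4 tumor cells, and at 32.2 CPM in Cd8 and 0.667 CPM in Cd4 lymph node cells. Ighm, the immunoglobulin heavy chain gene of B cells, was seen in 60.2% of Cd4 and 64.4% of Cd8 lymph node cells, and in 10.8% of Cd4 and 2.90% of Tdp tumor cells. At 2000 UMIs per cell these shares were 34.2%, 31.6%, 5.13% and 1.31%.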
